A study of Mus musculus with 18 samples.

How the data were processed

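The series measures polyA RNA of mouse (C57BL/6) leukemia cells transformed by MLL-AF9, MLL-AF6 or MLL-AF1p. Per the labels' protocols, cells were plated at a fixed density and treated for 6 days with 6 µM MI-2-2 or with DMSO at 0.25%. On day 3 the medium was changed, viable cells were brought back to the same density and the compound was given again. RNA of integrity number 8 or more went into TruSeq mRNA v2 libraries, a kit that does not mark the strand, so reads of genes overlapping on opposite strands are not told apart. Sequencing was on an Illumina HiSeq, and the labels give both a single-end and a paired-end run, so read layout is left open here.

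The values are RPKM as given by the authors in one table of 23418 genes by 18 libraries, with the gene length beside them per the file headers. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.0.0.7, HTSeq, edgeR and the mm9 genome, without saying what each was used for. RPKM times length in kilobases summed to the same total in every library, so the authors scaled to the reads counted to the listed genes. RPKM times length was also a whole multiple of one step per library for 100% of the values within a tolerance of 0.05, which gave the whole reads per gene and the depth per library. Depth ran from 21.18 to 56.3 M counted reads, and 10257 to 10494 genes per library reached an RPKM of 1. MLL-AF1p libraries were the deepest, while those of MLL-AF9 and MLL-AF6 overlapped in depth. With reads thinned to the smallest library, 429 of 432 tests of named genes and 64 of 66 list tests gave the same call. Replicate pairs of one group correlated at r = 0.972 to 0.998 across genes, which are not independent replicates, and differed by 3.95 to 76.1 times the spread of read counting alone (chi-square per degree of freedom).

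All 23418 names were unique, 21962 matched a current symbol and 1314 more an older one. The older names Mll1 (now Kmt2a), Mllt4 (the AF6 gene) and Chi3l3 are kept as the authors gave them. The names of 25 rows were 5-digit numbers, 19 of them among the genes kept, and these genes are counted and never named. Rn45s was the highest gene in 15 libraries. Because the reference used here is a later genome build than that of the authors, no positions are given. Near-identical paralogs and processed pseudogenes (Bcl2a1b and Bcl2a1d, the Stfa and Ear genes, Fth1 and Ftl1, ribosomal protein genes) can exchange reads. Reads of the fusion constructs are not separated from those of Mll1 and the partner genes.

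Groups came from the labels: 3 constructs by 2 treatments with 3 libraries each and none left out. Genes with RPKM of at least 1 in at least 3 of the 18 libraries were kept, 11238 in all. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with one fit of 6 group means, 12 residual degrees of freedom, a trended prior variance and Benjamini-Hochberg adjustment within each comparison. A gene is said to rise or fall where the adjusted p was under 0.05. Fold changes are differences of mean log2(RPKM + 0.5) and so understate the change of low genes. The comparisons were MI-2-2 against DMSO in each construct, the difference of that effect between constructs in pairs and by an F test, and the constructs against each other under DMSO. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

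Gene sets were 23 lists written from general knowledge of these cells and pathways, of which 22 kept at least 4 genes and were tested, 66 tests over the 3 constructs adjusted together. The list test was camera in limma with a preset correlation of 0.01 between genes, with the correlation estimated from the data and fry as alternatives. Of the 66, 26 passed with the preset correlation, 6 with the estimated one and 49 by fry. Counts per list use the adjustment over all genes, and counts adjusted over the list alone are given where they differ.

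Groups, comparisons, the list test, the rule for naming genes and the other settings to try were set before the data were examined. The rule names 6 rises and 6 falls per construct with all 3 treated libraries beyond all 3 controls and a mean RPKM of at least 5 in the higher group, up to 4 genes per list by mean size of change, 13 genes fixed by interest, 6 rises and 6 falls shared by all constructs, 6 genes of largest range of response, and 3 genes on each side of each DMSO comparison. It gave 131 genes, and predicted genes without a proper name were counted but not named. A few genes that the rule names are not reported here.

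The other settings were a pseudocount of 0.1, no filter on low values, median centring, quantile normalization, a constant prior variance, a block for replicate numbers, each library left out, each construct fitted alone, the 9 DMSO libraries alone, and the 2 other list tests. Further alternatives were added after seeing the data: voom in limma on the reads recovered, reads thinned to the smallest library, and libraries numbered 1 or numbered 2 left out of every group. Against voom, 96.5% of the calls in MLL-AF9, 97.1% in MLL-AF6 and 99.9% in MLL-AF1p were kept in the same direction.

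The scripts were tested on simulated data, reads drawn independently for each gene from its mean, its spread and the real depths, with known changes added in one group, over 10895 genes. In the MLL-AF9 comparison 20.4% of genes changed 1.25-fold, 56.0% of those changed 1.5-fold, 75.5% of those changed 2-fold and 93.9% of those changed 4-fold were called. Only 200 genes were changed, against 6339 called in the real MLL-AF9 comparison. The adjustment is stricter with few changed genes, so these shares are not the power of the real test. Of 10698 unchanged genes 6 were called, and of 200 unchanged lists 0 were called, which says nothing of correlated genes.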

Results

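PolyA RNA was sequenced from mouse leukemia cells transformed by MLL-AF9, MLL-AF6 or MLL-AF1p and cultured for 6 days with 6 µM MI-2-2, a small-molecule inhibitor of the menin-MLL interaction, or with DMSO. Each of the 6 groups had 3 libraries, 18 in all, and expression was read as the authors' RPKM. Depth, in units of 1 M (1000000) counted reads per library, was 21.97 to 29.06 in MLL-AF9 DMSO, 21.18 to 28.43 in MLL-AF9 MI-2-2, 27.94 to 30.25 in MLL-AF6 DMSO, 21.97 to 30.67 in MLL-AF6 MI-2-2, 48.88 to 56.3 in MLL-AF1p DMSO and 50.7 to 52.88 in MLL-AF1p MI-2-2. MLL-AF1p libraries were therefore the deepest, and comparisons of that construct with the other 2 carry a difference of depth. The labels give 3 replicates per group without saying that they are separate cultures, so every p-value below measures only the spread between these libraries, which may be technical.

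The 18 libraries separated first by treatment and second by construct. PC1 held 42.3% of the variance, with DMSO scores from −44.83 to −24.42 and MI-2-2 scores from 21.44 to 50.15. PC2 held 28.6%, with MLL-AF9 from 33.2 to 44.67, MLL-AF6 from −20.95 to −6.933 and MLL-AF1p from −34.81 to −22. Neutrophil calprotectin was a visible part of the treated libraries. S100a8 and S100a9 together took 0.140 ± 0.0238% of counted reads in MLL-AF9 DMSO and 1.08 ± 0.0867% with MI-2-2 (SD, n = 3), 0.0918 ± 0.0150% and 0.710 ± 0.05% in MLL-AF6, and 0.122 ± 0.0106% and 1.17 ± 0.102% in MLL-AF1p. Ribosomal protein genes took 10.8 ± 1.22% in MLL-AF9 DMSO and 5.50 ± 0.0471% with MI-2-2, 6.63 ± 0.830% and 4.69 ± 0.378% in MLL-AF6, and 8.16 ± 0.184% and 5.97 ± 0.0772% in MLL-AF1p. The 10 highest genes took 4.57 ± 0.175% in MLL-AF6 DMSO and 8.42 ± 0.610% with MI-2-2, where the lysosomal gene Psap or the ferritin gene Ftl1 led. Histone genes took a small share that was higher with MI-2-2, at 0.0226 ± 0.00323% and 0.0366 ± 0.00402% in MLL-AF9, 0.00722 ± 0.00171% and 0.0153 ± 0.00291% in MLL-AF6, and 0.00530 ± 0.000250% and 0.00740 ± 0.000407% in MLL-AF1p (DMSO, then MI-2-2; SD, n = 3). Small nucleolar RNA and microRNA genes took 0.0207 ± 0.000961% in MLL-AF6 DMSO and 0.0153 ± 0.000171% with MI-2-2.

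**Figure D1:**
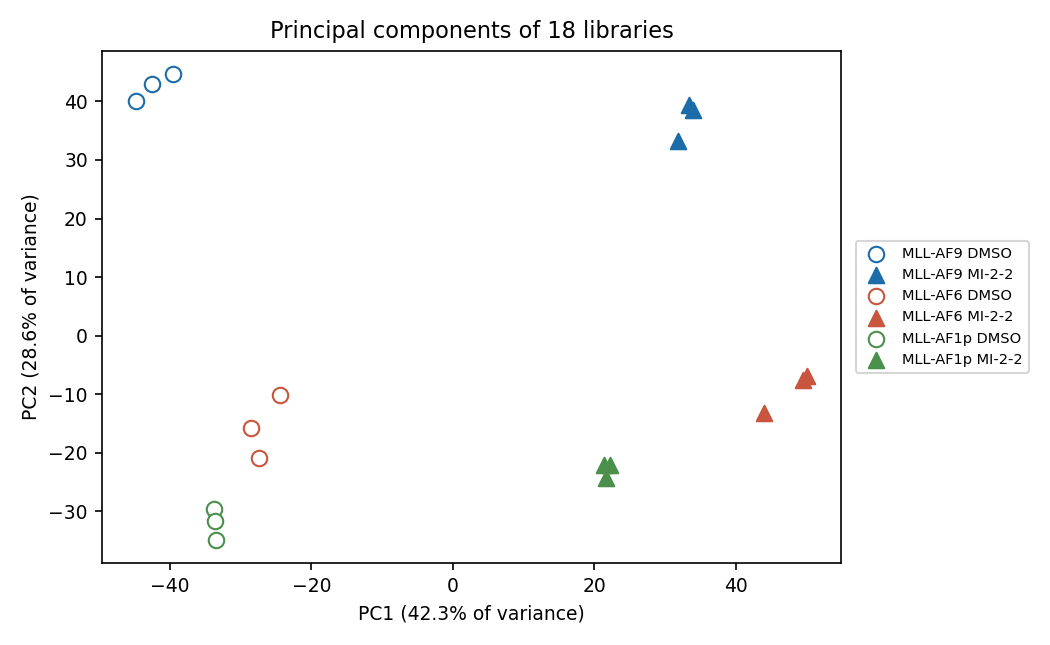
Scores of the 18 libraries on PC1 (horizontal) and PC2 (vertical), with open circles for DMSO, filled triangles for MI-2-2 and one color per construct. Treatment separates the libraries from left to right, and MLL-AF9 lies above the other 2 constructs.

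The first question was whether MI-2-2 lowers the genes that MLL fusions are known to bind, and whether it does so with each fusion partner. Meis1, a homeobox cofactor needed for MLL-rearranged leukemia, fell from 5.76 ± 0.694 to 0.342 ± 0.0427 RPKM in MLL-AF9 cells (SD, n = 3), from 29.5 ± 1.11 to 4.59 ± 0.131 in MLL-AF6 cells and from 24.1 ± 0.0684 to 6.12 ± 0.136 in MLL-AF1p cells. Its log2 fold changes were −2.89, −2.56 and −1.89 (limma, Benjamini-Hochberg adjusted p = 1.0e-13, 2.04e-13 and 2.35e-11). Hoxa9, its partner in self-renewal, fell from 38.0 ± 8.34 to 24.8 ± 0.103 in MLL-AF9, from 81.2 ± 7.51 to 27.1 ± 2.75 in MLL-AF6 and from 81.3 ± 3.67 to 49.0 ± 0.949 in MLL-AF1p. Its log2 fold changes were −0.58, −1.57 and −0.72 (limma, Benjamini-Hochberg adjusted p = 0.000443, 1.56e-08 and 0.000108). Hoxa10 fell from 38.4 ± 6.46 to 24.7 ± 1.03 (−0.61) in MLL-AF9, from 69.3 ± 2.08 to 20.9 ± 0.723 (−1.70) in MLL-AF6 and from 70.7 ± 1.30 to 27.5 ± 0.633 (−1.35) in MLL-AF1p, and Hoxa5 fell (−1.04, −2.58 and −1.36).

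Other genes of the same list fell in all 3 constructs too. The cell cycle kinase gene Cdk6 fell from 27.0 ± 5.66 to 14.5 ± 0.817 in MLL-AF9 (−0.86), from 28.6 ± 2.47 to 10.9 ± 0.467 in MLL-AF6 (−1.35) and from 35.4 ± 3.40 to 20 ± 0.444 in MLL-AF1p (−0.80; SD, n = 3). Myb, a transcription factor of progenitors, fell from 67.5 ± 4.01 to 20.1 ± 0.792 (−1.72), from 49.4 ± 5.04 to 19.0 ± 2.98 (−1.36) and from 57.5 ± 0.251 to 43.4 ± 0.767 (−0.40). Mef2c did not follow the fusion set in MLL-AF9 cells: it rose from 0.0791 ± 0.0226 to 1.69 ± 0.404 there (1.90), and fell from 9.37 ± 0.526 to 2.22 ± 0.200 in MLL-AF6 (−1.86) and from 8.28 ± 0.482 to 2.85 ± 0.128 in MLL-AF1p (−1.39). The receptor gene Flt3 was below the filter on low values, at 0.436 ± 0.22 and 0.00956 ± 0.0166 in MLL-AF9, 0.729 ± 0.350 and 0.0271 ± 0.0150 in MLL-AF6, and 0.626 ± 0.137 and 0.0441 ± 0.0246 in MLL-AF1p, and was not tested.

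Of the 24 MLL fusion target genes, 4 rose, 16 fell and 4 did not pass in MLL-AF9 cells, 1 rose, 19 fell and 4 did not pass in MLL-AF6 cells, and 2 rose, 21 fell and 1 did not pass in MLL-AF1p cells. Adjusted over the list alone, the MLL-AF6 counts were 2 and 19. The median log2 fold changes of the list were −0.62, −1.30 and −0.78. The list was called lower in each construct by camera in limma with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 0.00297, 8.19e-06 and 2.45e-07). None of the 3 calls held with the correlation estimated from the data (camera in limma, adjusted p = 0.455, 0.246 and 0.183 with an estimated correlation).

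The genes of the menin and MLL1 complex and of the fusion partners were not called as a set. Men1, which encodes the protein MI-2-2 keeps from MLL, fell from 10.6 ± 1.16 to 7.40 ± 0.562 in MLL-AF9 (−0.49) and from 7.62 ± 1.15 to 4.99 ± 0.280 in MLL-AF6 (−0.56), and was 7.24 ± 0.886 and 6.91 ± 0.238 in MLL-AF1p (SD, n = 3; −0.06, limma, Benjamini-Hochberg adjusted p = 0.701). Mll1, the gene now called Kmt2a, rose in MLL-AF9 (0.37), fell in MLL-AF6 (−0.33) and was at −0.15 in MLL-AF1p, where it did not pass. The elongation factor gene Mllt1 fell in MLL-AF9 (−0.81) and MLL-AF6 (−0.79). Mllt4, the gene of the AF6 partner, rose from 0.621 ± 0.120 to 1.14 ± 0.321 in MLL-AF9 (0.53) and fell from 3.81 ± 0.119 to 1.57 ± 0.0727 in MLL-AF6 (−1.06) and from 3.50 ± 0.439 to 1.19 ± 0.0570 in MLL-AF1p (−1.24). Aff4, an elongation complex gene, rose in MLL-AF9 (0.60) and was at 0.32 and 0.29 in the others, which passed with median centring (limma, Benjamini-Hochberg adjusted p = 0.0156 and 0.0446). Hcfc1, a cofactor of the MLL1 complex, rose in MLL-AF9 (0.43) and MLL-AF1p (0.46) and fell in MLL-AF6 (−0.24), where its call ended with median centring (limma, adjusted p = 0.0794), with quantile normalization (adjusted p = 0.128) and without MLL-AF6 MI-2-2 replicate 1 (adjusted p = 0.0597), replicate 3 (0.052) or MLL-AF6 DMSO replicate 3 (0.0512). Of 19 genes, 8 rose and 5 fell in MLL-AF9, 0 and 12 in MLL-AF6 and 4 and 5 in MLL-AF1p, with the rest not passing (camera in limma, Benjamini-Hochberg adjusted p = 0.982, 0.0843 and 0.949). Adjusted over the list alone, 1 gene rose in MLL-AF6. There the list was called lower with no filter on low values (camera in limma, adjusted p = 0.0094) and without MLL-AF6 DMSO replicate 2 (adjusted p = 0.0413). In MLL-AF9 the median, mean and test of this list did not share one sign.

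The second question was which blood cell genes change when these cells meet MI-2-2. Monocyte and macrophage markers rose in every construct. Csf1r, the receptor of macrophage growth factor, rose from 1.60 ± 0.0726 to 80.6 ± 21.1 in MLL-AF9 (5.24), from 2.83 ± 0.834 to 54.2 ± 16.0 in MLL-AF6 (4.02) and from 1.12 ± 0.0769 to 23.2 ± 1.30 in MLL-AF1p (3.88; SD, n = 3). Gpnmb, a membrane glycoprotein of macrophages, rose from 5.70 ± 2.89 to 705 ± 72.7 (6.92), from 53.6 ± 5.72 to 1320 ± 206 (4.60) and from 7.66 ± 0.327 to 165 ± 11.1 (4.34). Ctss, a lysosomal protease, rose by 6.09, 4.80 and 4.06, and the mannose receptor gene Mrc1 by 2.67, 5.96 and 4.10. The integrin gene Itgam rose from 31.9 ± 5 to 148 ± 5.81 (2.21), from 75.3 ± 6.26 to 161 ± 7.69 (1.09) and from 57.2 ± 2.03 to 97.4 ± 1.74 (0.76). Cd14, a receptor for bacterial lipopolysaccharide, rose in MLL-AF9 (1.39) and MLL-AF1p (1.26) and was at 0.97 in MLL-AF6 without passing (limma, Benjamini-Hochberg adjusted p = 0.0124, 0.0264 and 0.0664). Single libraries decided these calls: without MLL-AF6 DMSO replicate 1 it passed in MLL-AF6 (limma, adjusted p = 0.0115), and without MLL-AF9 DMSO replicate 2 it did not in MLL-AF9 (adjusted p = 0.0639). In MLL-AF1p the call ended without any 1 of 5 of its 6 libraries (limma, adjusted p from 0.0565 to 0.0702).

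Of 20 monocyte and macrophage markers, 15 rose and 0 fell in MLL-AF9, 16 and 1 in MLL-AF6, and 18 and 0 in MLL-AF1p, leaving 5, 3 and 2 that did not pass. Adjusted over the list alone, 17 rose and 1 fell in MLL-AF6. The medians were 2.03, 1.64 and 2.20, and the list was called higher in each construct (camera in limma with a preset correlation, Benjamini-Hochberg adjusted p = 1.79e-08, 4.87e-14 and 5.66e-14). These calls held with the correlation estimated (camera in limma, adjusted p = 0.0194, 0.00427 and 0.00427 with an estimated correlation).

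Genes of secondary and tertiary granules and of mature neutrophils rose the most of all lists. Lactoferrin, Ltf, rose from 0.872 ± 0.318 to 133 ± 24 in MLL-AF9 (6.61), from 1.54 ± 0.535 to 123 ± 16.4 in MLL-AF6 (5.95) and from 4.88 ± 0.573 to 216 ± 12.4 in MLL-AF1p (5.33; SD, n = 3). The antimicrobial peptide gene Camp rose from 6.32 ± 4.74 to 387 ± 49.9 (6.04), from 6.79 ± 1.37 to 169 ± 39.8 (4.53) and from 40.6 ± 6.43 to 1120 ± 32.6 (4.79). The collagenase gene Mmp8 rose by 7.18, 5.05 and 5.12, and Chi3l3, a chitinase-like gene with close paralogs, by 6.17, 4.59 and 6.53. Of 20 genes, 20 rose in MLL-AF9, 19 in MLL-AF6 and 18 in MLL-AF1p, none fell, and the medians were 3.65, 2.68 and 2.90. Adjusted over the list alone, 20 rose in MLL-AF6. As a list they were called higher in each construct (camera in limma with a preset correlation, Benjamini-Hochberg adjusted p = 4.03e-14, 2.99e-16 and 3.11e-16). With an estimated correlation the MLL-AF9 call ended (camera in limma, adjusted p = 0.0503 with an estimated correlation) and the other 2 held (adjusted p = 0.0358 in both).

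Primary granule genes did not move with the later granule genes. The neutrophil elastase gene Elane fell from 4920 ± 1030 to 1090 ± 76.2 in MLL-AF9 (−2.16) and from 2260 ± 122 to 917 ± 112 in MLL-AF6 (−1.31), and was 3750 ± 1030 and 2920 ± 191 in MLL-AF1p (−0.32; SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.158). The protease genes Prtn3 (−1.47 and −1.05) and Ctsg (−0.77 and −1.23) fell in MLL-AF9 and MLL-AF6 and were at 0.14 and −0.04 in MLL-AF1p, where neither passed. With quantile normalization Elane passed as a fall (−0.94, limma, Benjamini-Hochberg adjusted p = 0.00809) and Prtn3 as a rise (0.43, adjusted p = 0.00971) in MLL-AF1p, and without MLL-AF1p DMSO replicate 2 Elane was at −0.57 (adjusted p = 0.00683). Myeloperoxidase, Mpo, rose from 0.185 ± 0.193 to 6.72 ± 3.96 in MLL-AF6 (3.27) and from 35.4 ± 9.18 to 237 ± 14.0 in MLL-AF1p (2.76), and was 0.369 ± 0.135 and 0.243 ± 0.0871 in MLL-AF9 (−0.22, not passing). Of 10 genes, 2 rose and 5 fell in MLL-AF9, 2 and 7 in MLL-AF6, and 2 and 0 in MLL-AF1p, and the list was not called (camera in limma, Benjamini-Hochberg adjusted p = 0.0847, 0.268 and 0.581). Without MLL-AF9 DMSO replicate 1 it was called lower in MLL-AF9 (camera in limma, adjusted p = 0.0253). In MLL-AF1p its median, mean and test did not share one sign.

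**Figure D2:**
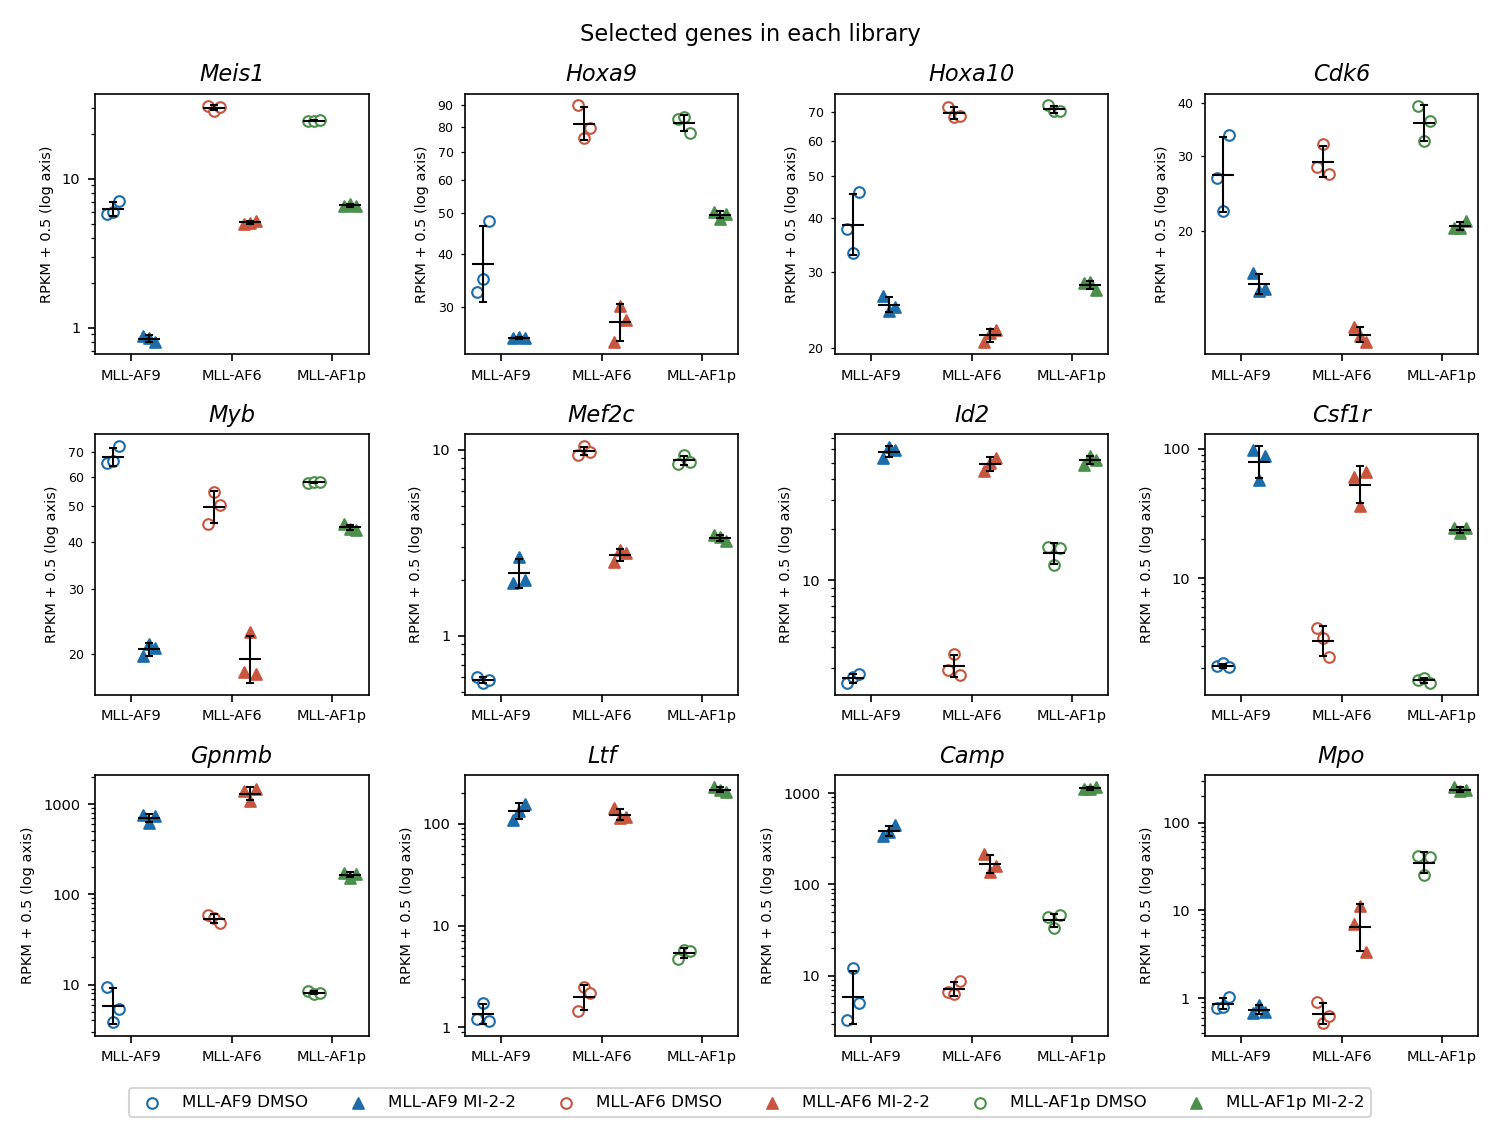
RPKM + 0.5 on a log axis for 12 genes, with one point per library, open circles for DMSO, filled triangles for MI-2-2, and black bars for the mean ± SD of the log2 values in each group of 3. Meis1, Hoxa9, Hoxa10, Cdk6 and Myb fall in every construct, while Id2, Csf1r, Gpnmb, Ltf and Camp rise.

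Stem and progenitor genes fell more often than they rose. Meis1, Hoxa9, Myb, Sox4 and Lmo2 of this list are also MLL fusion target genes, so its fall is in part the one given above. Only 12 of the 20 listed genes passed the filter on low values, and Cd34, Gata2, Erg and Hlf were among those that did not. Angpt1, a ligand of the Tek receptor on stem cells, fell from 1.09 ± 0.754 to 0.0272 ± 0.0242 in MLL-AF9 (−1.46), from 2.90 ± 0.995 to 0.136 ± 0.0734 in MLL-AF6 (−2.39) and from 3.61 ± 0.832 to 0.354 ± 0.0598 in MLL-AF1p (−2.25; SD, n = 3). Msi2, an RNA-binding protein gene of stem cells, fell (−1.15, −1.36 and −1.13). Kit, the stem cell factor receptor gene, rose slightly in MLL-AF9 (0.36) and MLL-AF6 (0.38) and was at 0.18 in MLL-AF1p. The Kit call in MLL-AF9 ended with median centring (limma, Benjamini-Hochberg adjusted p = 0.0529) and quantile normalization (adjusted p = 0.0655), and without any of 4 libraries of that construct (from 0.0516 to 0.087). In MLL-AF6 it ended without MI-2-2 replicate 1 or 2 (limma, adjusted p = 0.0556 and 0.0811). Of 12 genes, 4 rose and 7 fell in MLL-AF9, 2 and 8 in MLL-AF6, and 0 and 8 in MLL-AF1p, or 0 and 9 in MLL-AF1p adjusted over the list alone. As a list, these genes were called lower in MLL-AF1p (median −0.58, camera in limma, Benjamini-Hochberg adjusted p = 0.00428, and 0.222 with an estimated correlation), with adjusted p = 0.0794 in MLL-AF9 and 0.0511 in MLL-AF6. It was called lower in MLL-AF6 with median centring (camera in limma, adjusted p = 0.0198) and in MLL-AF9 with no filter on low values (adjusted p = 0.0479). A call in one construct and not in another is not a test of a difference between them.

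Id2, a member of the MLL fusion target list, and several macrophage genes also rose in all 3 constructs. Id2, an inhibitor of helix-loop-helix factors, rose from 2.12 ± 0.164 to 57.6 ± 4.26 in MLL-AF9 (4.47), from 2.60 ± 0.493 to 48.8 ± 4.49 in MLL-AF6 (4.00) and from 14.0 ± 1.92 to 51.2 ± 3.01 in MLL-AF1p (1.84; SD, n = 3). Clec4n, the gene of dectin-2, rose from 0.217 ± 0.119 to 98.4 ± 0.927 (7.12), from 0.518 ± 0.218 to 168 ± 16.7 (7.39) and from 0.510 ± 0.165 to 46.4 ± 1.34 (5.55). The chemokine gene Ccl2 rose by 6.71, 7.89 and 5.81, Ccl7 by 3.91, 6.99 and 5.37, and Ccl6 by 6.80, 4.93 and 2.38. Atp6v0d2, a subunit of the vacuolar proton pump, rose by 6.02, 7.37 and 4.79, Chi3l1 by 4.87, 5.51 and 5.38, and the lipase gene Lpl by 7.04, 4.07 and 4.11. Stfa3, one of a cluster of similar stefin genes, rose by 6.84, 5.71 and 4.56.

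Falls shared by the 3 constructs were smaller in fold. Hpgd, which inactivates prostaglandins, fell from 1710 ± 254 to 108 ± 12.9 in MLL-AF9 (−3.97), from 2660 ± 103 to 137 ± 28.0 in MLL-AF6 (−4.29) and from 2070 ± 268 to 209 ± 16.7 in MLL-AF1p (−3.30; SD, n = 3). Ifitm1, a membrane protein gene, fell from 1740 ± 226 to 343 ± 36.9 (−2.34), from 835 ± 36.1 to 138 ± 13.9 (−2.60) and from 519 ± 17.5 to 117 ± 4.25 (−2.15). The growth factor gene Fgf10 fell (−2.65, −3.77 and −2.87), the myosin kinase gene Mylk (−3.26, −3.27 and −2.37), the cation transporter gene Slc22a3 (−3.46, −2.92 and −2.42), and Gpx8, a peroxidase of the endoplasmic reticulum, (−3.44, −2.35 and −2.44). Akr1c18, a steroid dehydrogenase gene with close paralogs, fell (−3.67, −4.74 and −1.96).

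The largest falls of single constructs included further genes. Mab21l2 fell from 52.1 ± 5.79 to 3.97 ± 0.225 in MLL-AF9 (−3.55; SD, n = 3) and from levels under 1 RPKM in the others (−0.74 and −1.08). Igfbp7 went from 18 ± 20.4 to 0.578 ± 0.338 in MLL-AF9 (−3.46, limma, Benjamini-Hochberg adjusted p = 0.000512; −2.52 without DMSO replicate 1 and −4.32 without DMSO replicate 2) and was at −0.63 and −0.34 in MLL-AF6 and MLL-AF1p, where it did not pass, although in MLL-AF1p it did with that construct fitted alone (adjusted p = 0.0321). Il2ra, the interleukin-2 receptor gene, fell (−1.32, −3.61 and −3.08), C2cd4a (−1.47, −3.73 and −1.44), and the retinoic acid synthesis gene Aldh1a3 (−0.79, −2.17 and −3.32). In MLL-AF9, Aldh1a3 ranged from 0.293 to 0.504 RPKM under DMSO and from 0.0103 to 0.0212 with MI-2-2. At such levels the 0.5 added to RPKM keeps the fold change small. The Wnt antagonist gene Frzb fell in MLL-AF6 (−3.30) and MLL-AF1p (−3.14) and was near 0 RPKM in MLL-AF9 (−0.15).

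Cell cycle genes did not fall as a set. The mitotic checkpoint kinase gene Bub1 rose from 4.74 ± 0.566 to 10.4 ± 0.749 in MLL-AF9 (1.06) and from 5.87 ± 0.656 to 8.70 ± 0.311 in MLL-AF6 (0.53), and was 11.5 ± 0.842 and 12.0 ± 0.298 in MLL-AF1p (0.06; SD, n = 3). Ccna2 rose by 0.90 and 0.53 and was at 0.23 in MLL-AF1p, and Foxm1, a factor of the G2 phase, rose by 0.87 and 0.62 and was at 0.18 in MLL-AF1p. With median centring both passed in MLL-AF1p too (limma, Benjamini-Hochberg adjusted p = 0.0482 and 0.046). Ccnd1 rose from low levels in MLL-AF6 (0.89) and MLL-AF1p (1.35). It passed narrowly in MLL-AF9 (0.32, limma, Benjamini-Hochberg adjusted p = 0.0400), where the call ended with median centring (adjusted p = 0.110) and quantile normalization (adjusted p = 0.544), and without any of 5 libraries (from 0.0505 to 0.160). Of 34 genes, 24 rose and 0 fell in MLL-AF9, 11 and 1 in MLL-AF6, and 8 and 2 in MLL-AF1p, with medians of 0.38, 0.14 and 0.18. The list was called higher in each construct (camera in limma with a preset correlation, Benjamini-Hochberg adjusted p = 9.34e-05, 7.12e-04 and 0.00476). No call held with the correlation estimated (camera in limma, adjusted p = 0.494, 0.626 and 0.655 with an estimated correlation), and the MLL-AF1p call ended without MLL-AF1p DMSO replicate 2 (adjusted p = 0.0542).

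Myc and most genes of ribosome biogenesis fell in MLL-AF9 and MLL-AF6 cells. Myc fell from 36.2 ± 8.08 to 14.0 ± 0.272 in MLL-AF9 (−1.32) and from 20 ± 7.29 to 10.4 ± 3.23 in MLL-AF6 (−0.88), and was 21.9 ± 0.177 and 15.4 ± 0.491 in MLL-AF1p (−0.49; SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0984). With each construct fitted alone the MLL-AF6 fall did not pass (limma, adjusted p = 0.0581) and the MLL-AF1p fall did (adjusted p = 6.81e-05), as it did without MLL-AF6 DMSO replicate 1 (adjusted p = 0.0344). Dkc1, a pseudouridine synthase of the nucleolus, fell (−0.51 and −1.15) and was at −0.14 in MLL-AF1p. Wdr12 fell (−0.75, −0.83 and −0.51), while Bop1, its partner in processing ribosomal RNA, fell (−0.44 and −0.72) and rose by 0.62 in MLL-AF1p. The Wdr12 call in MLL-AF1p ended without MLL-AF1p DMSO replicate 2 (limma, adjusted p = 0.0824) or MI-2-2 replicate 3 (0.0517). Of 22 genes, 0 rose and 17 fell in MLL-AF9 (18 adjusted over the list alone), 0 and 21 in MLL-AF6, and 6 and 1 in MLL-AF1p. By camera, the set was called lower in MLL-AF9 (median −0.49) and MLL-AF6 (median −0.70; camera in limma, Benjamini-Hochberg adjusted p = 6.4e-04 in both, and 0.655 with an estimated correlation), and not in MLL-AF1p (adjusted p = 0.241).

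Ribosomal protein genes fell together. Rpl5 fell from 1140 ± 145 to 491 ± 1.48 in MLL-AF9 (−1.20), from 664 ± 93.3 to 408 ± 29.2 in MLL-AF6 (−0.70) and from 910 ± 72.1 to 548 ± 11.7 in MLL-AF1p (−0.73; SD, n = 3). Rpl10a fell (−1.08, −0.58 and −0.58), as did Rps6 (−1.09, −0.60 and −0.56). Processed pseudogenes of these genes can share their reads. In the fixed list of 28 ribosomal protein and mitochondrial respiration genes, 2 rose and 22 fell in MLL-AF9, 6 and 14 in MLL-AF6, and 4 and 13 in MLL-AF1p. Adjusted over the list alone the falls were 23 in MLL-AF9 and 15 in MLL-AF1p. The set was called lower in MLL-AF9 (median −0.60, camera in limma, Benjamini-Hochberg adjusted p = 9.85e-08, and 0.25 with an estimated correlation), and not in MLL-AF6 (adjusted p = 0.852) or MLL-AF1p (adjusted p = 0.237).

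Inhibitors of cyclin-dependent kinases and p53 targets went both ways. Cdkn1c fell from 0.795 ± 0.0162 to 0.158 ± 0.0397 in MLL-AF9 (−0.98), rose from 0.175 ± 0.0790 to 3.46 ± 1.48 in MLL-AF6 (2.48) and was 0.299 ± 0.0646 and 0.430 ± 0.0322 in MLL-AF1p (0.22; SD, n = 3). Cdkn2c, an inhibitor of Cdk4 and Cdk6, rose by 1.64 and 0.76 and was at −0.28 in MLL-AF1p, where it passed without MLL-AF6 DMSO replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.0343 and 0.0287). The p53 target Sesn1 fell (−0.80, −1.19 and −0.70), and Phlda3 rose by 0.72 in MLL-AF6 and 1.18 in MLL-AF1p and was at 0.19 in MLL-AF9. Of 19 genes, 5 rose and 6 fell in MLL-AF9, 5 and 7 in MLL-AF6, and 5 and 5 in MLL-AF1p (camera in limma, Benjamini-Hochberg adjusted p = 0.965, 0.875 and 0.949). Median, mean and test of this list did not share one sign in any construct.

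Apoptosis regulators went both ways in each construct. Bcl2a1b, a survival gene with near-identical paralogs, rose from 1.96 ± 1.32 to 17.8 ± 2.61 in MLL-AF9 (3.02) and from 3.90 ± 1.27 to 22.4 ± 5.13 in MLL-AF6 (2.40), and was 1.93 ± 1.28 and 3.65 ± 0.445 in MLL-AF1p (0.88; SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0546). With median centring the MLL-AF1p rise passed (limma, adjusted p = 0.0479), as it did with quantile normalization (adjusted p = 0.0359), without MLL-AF1p DMSO replicate 2 (0.00807), and without MLL-AF9 DMSO replicate 1 or 2 or MLL-AF6 DMSO replicate 1 (from 0.0237 to 0.0458). Bcl2a1d rose by 2.52, 1.44 and 1.14. The pro-death gene Bmf fell (−1.19, −1.27 and −1.49). Of 20 genes, 13 rose and 4 fell in MLL-AF9 (14 and 4 adjusted over the list alone), 4 and 5 in MLL-AF6 (4 and 4), and 4 and 5 in MLL-AF1p. The list was called higher in MLL-AF9 (median 0.51, camera in limma, Benjamini-Hochberg adjusted p = 0.0211, and 0.0973 with an estimated correlation), and not in MLL-AF6 (adjusted p = 0.241) or MLL-AF1p (adjusted p = 0.888), where its median, mean and test did not share one sign.

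Interferon response genes moved in opposite directions in different constructs. Oas2, an antiviral synthetase with paralogs, rose from 4.77 ± 0.655 to 30.1 ± 6.89 in MLL-AF9 (2.52) and from 3.70 ± 0.212 to 5.99 ± 1.41 in MLL-AF1p (0.61), and fell from 7.56 ± 0.719 to 1.55 ± 0.484 in MLL-AF6 (−2.0; SD, n = 3). The Oas2 rise in MLL-AF1p did not pass without MLL-AF1p MI-2-2 replicate 3 (0.44, limma, Benjamini-Hochberg adjusted p = 0.099) or DMSO replicate 3 (adjusted p = 0.0525). Rtp4 rose from 0.262 ± 0.158 to 7.82 ± 4.48 in MLL-AF9 (3.31) and from 0.697 ± 0.284 to 5.97 ± 2.13 in MLL-AF1p (2.41), and fell from 2.23 ± 0.250 to 0.730 ± 0.0741 in MLL-AF6 (−1.15). Oasl2 rose by 2.82 in MLL-AF9 and 2.30 in MLL-AF1p and was at −0.50 in MLL-AF6, where it passed without MLL-AF6 DMSO replicate 1 (−0.69, limma, adjusted p = 0.0238). The chemokine gene Cxcl10, also a target of other inflammatory signals, rose in all 3 (2.54, 1.14 and 1.4).

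Of 24 interferon response genes, 23 rose and 0 fell in MLL-AF9, 2 rose and 15 fell in MLL-AF6, and 13 rose and 2 fell in MLL-AF1p, or 15 and 3 in MLL-AF1p adjusted over the list alone. As a set they were called higher in MLL-AF9 (median 1.54, camera in limma, Benjamini-Hochberg adjusted p = 4.28e-10, and 0.272 with an estimated correlation) and in MLL-AF1p (median 0.44, adjusted p = 7.4e-04, and 0.654 with an estimated correlation). In MLL-AF6 the median was −0.54 and the list was short of the threshold (camera in limma, adjusted p = 0.0561, and 0.866 with an estimated correlation), and it was called lower with median centring (adjusted p = 0.0235) and with quantile normalization (adjusted p = 0.0161). The response of the list was higher in MLL-AF9 than in MLL-AF6, with 23 genes higher and 0 lower and a median difference of 1.84 (camera in limma, Benjamini-Hochberg adjusted p = 1.61e-15, and 0.257 with an estimated correlation).

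**Figure D3:**
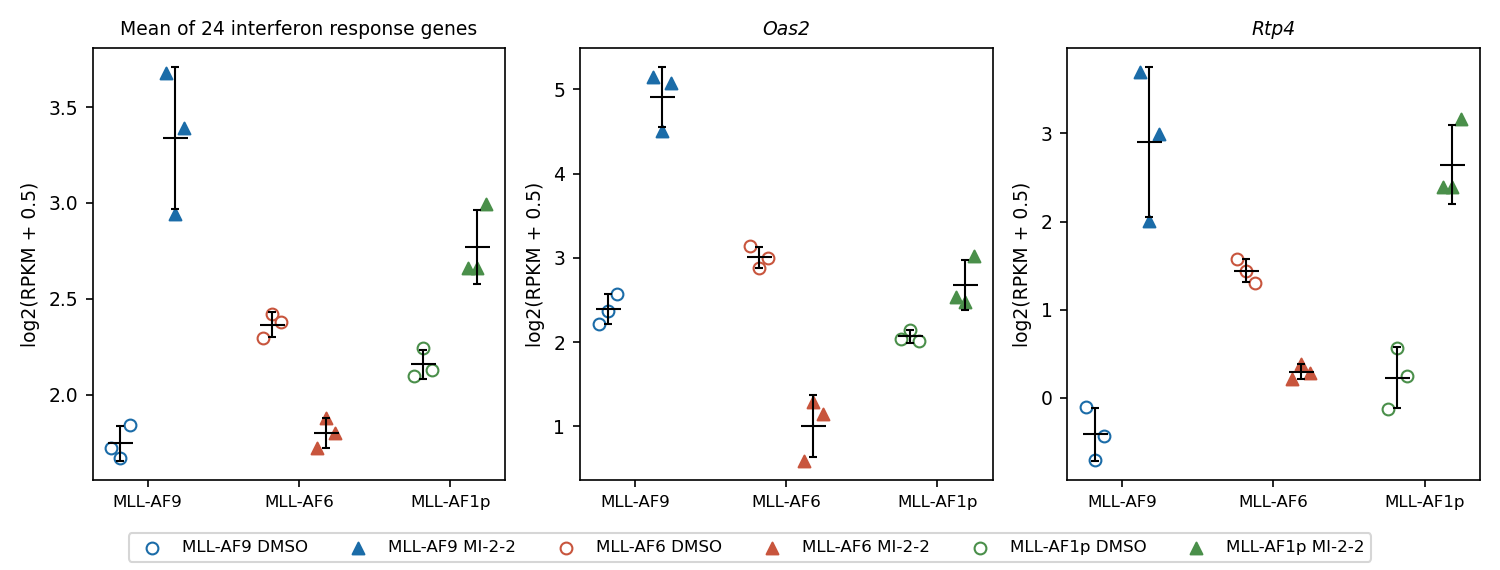
Mean log2(RPKM + 0.5) of 24 interferon response genes (left), Oas2 (middle) and Rtp4 (right) by construct, with one point per library, open circles for DMSO, filled triangles for MI-2-2, and bars for the mean ± SD of 3. The treated libraries lie above their controls in MLL-AF9 and MLL-AF1p and below them in MLL-AF6.

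The genes of antigen presentation did not move as one set. The invariant chain gene Cd74 rose from 0.247 ± 0.00721 to 27.3 ± 6.22 in MLL-AF9 (5.20), from 1.30 ± 0.770 to 20.2 ± 4.28 in MLL-AF6 (3.58) and from 0.804 ± 0.190 to 20 ± 0.635 in MLL-AF1p (3.98; SD, n = 3). The class II chain genes fell. H2-Aa fell from 2.31 ± 1.10 to 0.621 ± 0.194 in MLL-AF9 and by more in MLL-AF6 (−3.65) and MLL-AF1p (−3.29), and H2-Ab1 fell from 7.37 ± 3.51 to 0.983 ± 0.611 (−2.37), from 24.7 ± 3.83 to 2.80 ± 1.41 (−3.00) and, from 24.5 ± 1.72, in MLL-AF1p (−3.85). The H2-Ab1 fall differed between MLL-AF9 and MLL-AF1p (1.48, limma, Benjamini-Hochberg adjusted p = 0.0368) and not between MLL-AF6 and MLL-AF1p (0.86, adjusted p = 0.225). Irf4, a transcription factor of lymphoid and dendritic cells, rose by 2.16, 0.86 and 1.60. Of 10 genes, 4 rose and 5 fell in MLL-AF9 (4 and 6 adjusted over the list alone), 3 and 5 in MLL-AF6, and 4 and 6 in MLL-AF1p (camera in limma, Benjamini-Hochberg adjusted p = 0.943, 0.896 and 0.50). In MLL-AF9 the median of this list was −0.37 and its mean 0.36.

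Cholesterol synthesis genes rose in MLL-AF1p cells. Hmgcs1, an early enzyme of the pathway, rose from 54.4 ± 10.1 to 105 ± 4.91 in MLL-AF1p (0.96) and from 41.9 ± 7.63 to 78.5 ± 10.6 in MLL-AF9 (0.91), and was 47.5 ± 1.52 and 57.2 ± 3.89 in MLL-AF6 (0.26; SD, n = 3). Hsd17b7 rose by 1.16, 0.49 and 1.30, and Insig1, the sterol sensor partner, by 1.09 in MLL-AF9 and 0.96 in MLL-AF1p and was at 0.19 in MLL-AF6. In MLL-AF6, Hmgcs1 passed with median centring (limma, Benjamini-Hochberg adjusted p = 0.0412) and Insig1 without MLL-AF1p DMSO replicate 2 (adjusted p = 0.0344), and Hsd17b7 did not without MLL-AF6 MI-2-2 replicate 3 (adjusted p = 0.0608). Of 23 genes, 12 rose and 1 fell in MLL-AF9, 2 and 1 in MLL-AF6 (1 and 1 adjusted over the list alone), and 19 and 0 in MLL-AF1p (20 and 0). The list was called higher in MLL-AF1p (median 0.76, camera in limma, Benjamini-Hochberg adjusted p = 1.79e-08, and 0.44 with an estimated correlation). It was just short of the threshold in MLL-AF9 (adjusted p = 0.0511, and 0.0316 with median centring) and not called in MLL-AF6 (adjusted p = 0.204), where its median, mean and test did not share one sign.

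Of the stress responses, NRF2 and oxidative stress genes rose in all 3 constructs. Heme oxygenase, Hmox1, rose from 17.3 ± 7.32 to 59.4 ± 11.3 in MLL-AF9 (1.82), from 15.0 ± 1.29 to 114 ± 32.8 in MLL-AF6 (2.85) and from 18.6 ± 5.31 to 40.1 ± 1.70 in MLL-AF1p (1.13; SD, n = 3). The ferritin genes, which have many pseudogenes, rose as well, Fth1 by 2.42, 3.35 and 1.52 and Ftl1 by 1.44, 1.72 and 0.91. Slc7a11, a cystine transporter gene, rose in MLL-AF9 (1.97) and MLL-AF6 (2.60) and was at 0.47 in MLL-AF1p, where it passed without MLL-AF1p DMSO replicate 2 (0.72, limma, adjusted p = 0.0328). Of 19 NRF2 genes, 11 rose and 4 fell in MLL-AF9, 12 and 0 in MLL-AF6 (14 and 0 adjusted over the list alone), and 12 and 2 in MLL-AF1p (13 and 2), with medians of 0.51, 0.41 and 0.47. This set was called higher in each (camera in limma with a preset correlation, Benjamini-Hochberg adjusted p = 0.0211, 1.49e-07 and 1.36e-04). Only the MLL-AF6 call held with the correlation estimated (camera in limma, adjusted p = 0.272, 0.0194 and 0.0663 with an estimated correlation).

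ATF4 and amino acid stress genes were not called in any construct. Atf3, a stress-induced factor, rose from 0.331 ± 0.112 to 11.3 ± 0.157 in MLL-AF9 (3.84), from 2.43 ± 0.787 to 25 ± 1.18 in MLL-AF6 (3.15) and from 2.84 ± 0.575 to 8.58 ± 0.866 in MLL-AF1p (1.45; SD, n = 3). The pseudokinase gene Trib3 varied widely under DMSO and was at −1.72, −1.05 and −1.46 without passing, while without MLL-AF9 DMSO replicate 1 it passed in MLL-AF9 (−2.63, limma, Benjamini-Hochberg adjusted p = 0.00587). Cth, an enzyme of cysteine synthesis, went from 8.02 ± 8.46 to 0.348 ± 0.0935 in MLL-AF9 (−2.56, limma, Benjamini-Hochberg adjusted p = 0.0175), a call that ended without MLL-AF9 DMSO replicate 2 (−1.65, adjusted p = 0.104) or replicate 3 (adjusted p = 0.058), while without replicate 1 it was at −3.70 (adjusted p = 0.000421). Of 22 genes, 3 rose and 10 fell in MLL-AF9, 3 and 3 in MLL-AF6 (2 and 3 adjusted over the list alone), and 1 and 3 in MLL-AF1p (1 and 2; camera in limma, Benjamini-Hochberg adjusted p = 0.142, 0.665 and 0.529). Without MLL-AF9 DMSO replicate 1 the list was called lower in MLL-AF9 (camera in limma, adjusted p = 0.0109). Its median, mean and test did not share one sign in MLL-AF6.

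Glycolysis genes fell and heat shock genes rose in MLL-AF1p cells. Pgk1, which makes ATP in glycolysis, fell from 1470 ± 249 to 560 ± 56.7 in MLL-AF1p (−1.38) and was at −0.24 in MLL-AF9 and −0.30 in MLL-AF6, where it did not pass (SD, n = 3). Pdk1, a pyruvate dehydrogenase kinase gene, fell in MLL-AF1p (−1.44) and MLL-AF6 (−0.70) and was at −0.19 in MLL-AF9. Aldoc fell in MLL-AF9 (−0.61) and MLL-AF1p (−1.35) and was at −0.29 in MLL-AF6, and the muscle isoform gene Pfkm fell in all 3 (−0.69, −0.85 and −0.74). These calls moved with single libraries. Without MLL-AF6 DMSO replicate 1 Pgk1 fell in MLL-AF6 (−0.66, limma, Benjamini-Hochberg adjusted p = 0.017), and without libraries numbered 1 it fell in MLL-AF9 (−0.58, adjusted p = 0.0107). Without MLL-AF9 DMSO replicate 1 Pdk1 fell in MLL-AF9 (−0.49, limma, adjusted p = 0.0452), and its MLL-AF6 call ended without MLL-AF6 DMSO replicate 2 (adjusted p = 0.0767), DMSO replicate 3 (0.0528) or MI-2-2 replicate 1 (0.0519). The Aldoc call in MLL-AF9 ended without MLL-AF9 DMSO replicate 3 (−0.46, limma, adjusted p = 0.0824) or MI-2-2 replicate 2 (0.0618). Of 19 glycolysis genes, 3 rose and 3 fell in MLL-AF9, 1 and 5 in MLL-AF6 (1 and 3 adjusted over the list alone), and 0 and 12 in MLL-AF1p. As a list they were called lower in MLL-AF1p (median −0.49, camera in limma, Benjamini-Hochberg adjusted p = 0.00524, and 0.692 with an estimated correlation), and not in MLL-AF9 (adjusted p = 0.919), where median, mean and test did not share one sign, or in MLL-AF6 (adjusted p = 0.896).

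The chaperone gene Hspa8 rose from 748 ± 115 to 1410 ± 11.3 in MLL-AF1p (0.93) and Hsph1 from 13.7 ± 1.86 to 31.1 ± 0.618 (1.17; SD, n = 3). Hspa8 was at 0.12 and −0.13, and Hsph1 at 0.15 and −0.28, in MLL-AF9 and MLL-AF6, none of which passed. Without MLL-AF9 DMSO replicate 1 Hsph1 rose in MLL-AF9 (0.39, limma, Benjamini-Hochberg adjusted p = 0.00278) and fell in MLL-AF6 (adjusted p = 0.0103), and with quantile normalization Hspa8 rose in MLL-AF9 (0.35, adjusted p = 0.00494). Hspa5, of the endoplasmic reticulum, rose in MLL-AF9 (0.53) and MLL-AF1p (0.71), and Hsp90aa1 fell in MLL-AF9 (−0.37) and MLL-AF6 (−0.82). Of 11 heat shock genes, 3 rose and 2 fell in MLL-AF9, 0 and 3 in MLL-AF6 (0 and 2 adjusted over the list alone), and 6 and 0 in MLL-AF1p. The list was called higher in MLL-AF1p (median 0.37, camera in limma, Benjamini-Hochberg adjusted p = 0.00317, and 0.275 with an estimated correlation), and not in MLL-AF9 (adjusted p = 0.825) or MLL-AF6 (adjusted p = 0.814).

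**Figure D4:**
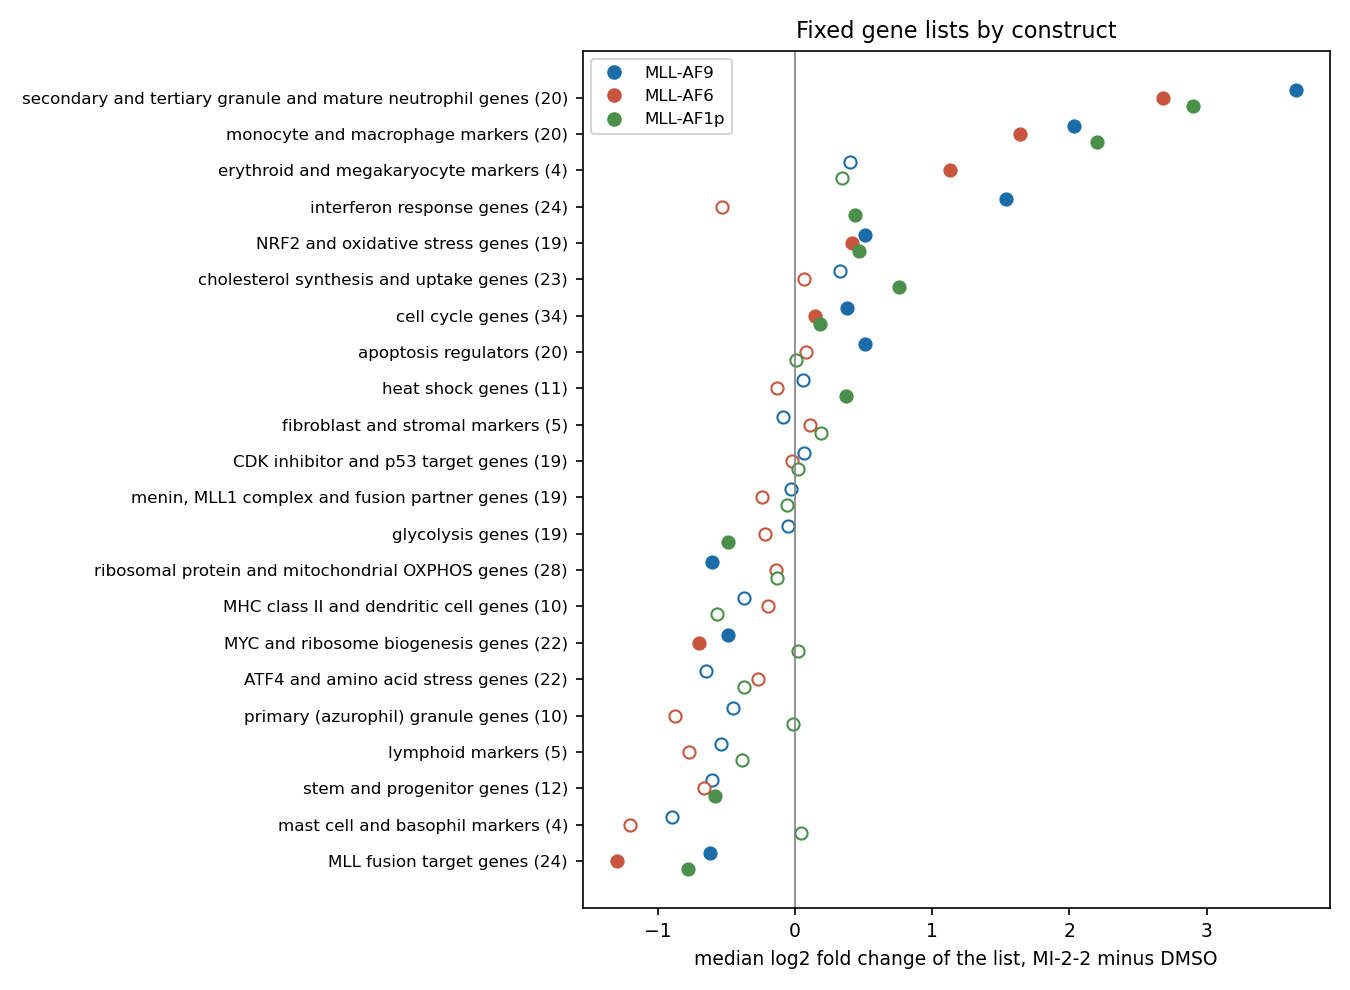
Median log2 fold change of each fixed gene list (rows, gene number in brackets) with MI-2-2, one point per construct. Filled points have adjusted p under 0.05 by camera with a preset correlation, and the neutrophil and monocyte lists lie farthest to the right.

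Markers of other cell types were measured too. Vwf, of megakaryocytes and endothelium, rose from 1.21 ± 0.156 to 3.82 ± 0.102 in MLL-AF9 (1.34), from 0.501 ± 0.0480 to 10.2 ± 1.05 in MLL-AF6 (3.41) and from 0.487 ± 0.0526 to 2.53 ± 0.163 in MLL-AF1p (1.62; SD, n = 3). The platelet factor gene Pf4 fell in MLL-AF9 (−1.42), rose in MLL-AF6 from 1.16 ± 0.318 to 3.46 ± 0.827 and was at 0.20 in MLL-AF1p. The transferrin receptor gene Tfrc fell in MLL-AF6 (−0.88), and Car2 rose in MLL-AF9 (0.66) and MLL-AF6 (1.02). The Car2 rise in MLL-AF9 ended with median centring (limma, Benjamini-Hochberg adjusted p = 0.0545) and quantile normalization (adjusted p = 0.128), and without MLL-AF9 DMSO replicate 1 (0.116), MI-2-2 replicate 1 (0.136) or MI-2-2 replicate 3 (0.0948). Of 4 erythroid and megakaryocyte markers, 2 rose and 1 fell in MLL-AF9, 3 and 1 in MLL-AF6, and 1 and 0 in MLL-AF1p (camera in limma, Benjamini-Hochberg adjusted p = 0.606, 0.0428 and 0.0847). The MLL-AF6 call (median 1.13) ended with an estimated correlation (camera in limma, adjusted p = 0.192 with an estimated correlation), median centring (adjusted p = 0.0741) and quantile normalization (adjusted p = 0.0657). It also ended with a block for replicate numbers (camera in limma, adjusted p = 0.0677).

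Among lymphoid markers, the interleukin-7 receptor gene Il7r rose in all 3 constructs (1.82, 4.17 and 1.89), and the T cell kinase gene Lck fell in all 3 (−0.54, −0.78 and −0.58). Igll1, of the surrogate light chain, fell in MLL-AF9 (−1.71) and MLL-AF6 (−1.78) and was at −0.38 in MLL-AF1p, and Cd79b fell in MLL-AF6 (−1.20) and MLL-AF1p (−0.71). Of 5 lymphoid markers, 1 rose and 3 fell in MLL-AF9 (1 and 4 adjusted over the list alone), 1 and 3 in MLL-AF6, and 1 and 2 in MLL-AF1p (2 and 2; camera in limma, Benjamini-Hochberg adjusted p = 0.345, 0.814 and 0.965). Among mast cell and basophil markers, the protease gene Mcpt8 (−1.14 and −1.57) and the proteoglycan gene Srgn (−1.45 and −1.76), which other blood cells also express, fell in MLL-AF9 and MLL-AF6, and Srgn also in MLL-AF1p (−0.90). Hdc, which makes histamine, did not pass in any construct (−0.65, −0.83 and 0.78), except in MLL-AF1p with that construct fitted alone (limma, Benjamini-Hochberg adjusted p = 0.00063). Of 4 mast cell and basophil markers, 1 rose and 2 fell in MLL-AF9, 1 and 2 in MLL-AF6, and 0 and 1 in MLL-AF1p (camera in limma, Benjamini-Hochberg adjusted p = 0.286, 0.47 and 0.888). Of the eosinophil markers, 3 passed the filter, too few for a list test. Ear6 rose by 1.74, 0.74 and 0.71, Ear2 by 1.53 in MLL-AF1p and Siglec5 by 0.45 in MLL-AF9, and the other values were 0.06 and 0.00 for Ear2 and 0.14 and −0.05 for Siglec5. Median, mean and test did not share one sign for lymphoid markers in MLL-AF6 and MLL-AF1p and for mast cell markers in MLL-AF1p.

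Among fibroblast and stromal markers, Thy1, also a marker of lymphoid cells, fell from 4.33 ± 2.14 to 0.652 ± 0.197 in MLL-AF9 (−1.99), from 1020 ± 298 to 165 ± 51.5 in MLL-AF6 (−2.63) and from 647 ± 22.6 to 242 ± 20.4 in MLL-AF1p (−1.42; SD, n = 3). The intermediate filament gene Vim rose by 2.31, 2.32 and 0.56, Fn1 rose by 2.45 in MLL-AF9 and 1.99 in MLL-AF1p from levels under 0.2 RPKM and was at 0.20 in MLL-AF6, and Pecam1 fell (−1.26, −1.29 and −1.05). Fn1 passed in MLL-AF6 with median centring (limma, Benjamini-Hochberg adjusted p = 0.025), and Vim did not in MLL-AF1p without libraries numbered 2 (adjusted p = 0.0955). Of 5 markers, 2 rose and 2 fell in MLL-AF9, 1 and 2 in MLL-AF6, and 2 and 2 in MLL-AF1p (camera in limma, Benjamini-Hochberg adjusted p = 0.888, 0.895 and 0.758). Median, mean and test of this list did not share one sign in MLL-AF9 and MLL-AF6.

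Across all genes, the sharing between constructs went beyond that of independent lists. In MLL-AF9, 3203 genes rose and 3136 fell, in MLL-AF6 2025 and 4377, and in MLL-AF1p 2150 and 2953, of 11238 tested (limma, Benjamini-Hochberg adjusted p under 0.05). These counts use one estimate of the spread per gene for all groups and gave 6339, 6402 and 5103 genes in total. With each construct fitted alone the totals were 4875, 5838 and 6852, so the order of the constructs by number called depends on the fit. At 2-fold or more, 771 rose and 446 fell in MLL-AF9, 671 and 402 in MLL-AF6, and 450 and 303 in MLL-AF1p. In all 3 constructs 971 genes rose and 1276 fell, against 110 and 321 if the 3 lists were independent, and 293 rose and 86 fell by at least 2-fold. The comparisons share that estimate of the spread, so calls can coincide beyond independent lists without a shared response, here and for pairs of constructs. The count of 86 was 161 with voom on reads recovered from the RPKM. The share of changed genes that rose in MLL-AF6 was 31.6%, and 41.9% with median centring, so the size of the excess of falls there depends on the scaling. In MLL-AF9 the counts became 2681 and 3828 with median centring, so the near balance there depends on it too. Log2 fold changes correlated across genes at r = 0.743 between MLL-AF9 and MLL-AF6, 0.708 between MLL-AF9 and MLL-AF1p, and 0.748 between MLL-AF6 and MLL-AF1p, where genes are not independent replicates.

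The same genes were often called in 2 constructs. MLL-AF9 and MLL-AF6 shared 1526 rises (577 if independent) and 2264 falls (1221), MLL-AF9 and MLL-AF1p 1382 rises (613) and 1563 falls (824), and MLL-AF6 and MLL-AF1p 1111 rises (387) and 1894 falls (1150). Opposite calls were 406, 379 and 419 for these 3 pairs. Without MLL-AF9 DMSO replicate 1 the 406 became 641, and without MLL-AF1p MI-2-2 replicate 1 the 419 became 249, so these counts move with single libraries.

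The third question was which genes answer differently by fusion partner, tested as the difference of log2 fold changes. The secreted glycoprotein gene Fstl1 rose from 0.675 ± 0.393 to 272 ± 68.3 in MLL-AF6 (7.87) and from 1.15 ± 0.116 to 33.1 ± 4.68 in MLL-AF1p (4.35), and was 0.307 ± 0.233 and 0.130 ± 0.0348 in MLL-AF9 (−0.32; SD, n = 3), a difference of −8.19 between MLL-AF9 and MLL-AF6. The gelatinase gene Mmp9 rose from 0.601 ± 0.208 to 31.9 ± 4.78 in MLL-AF9 (4.89), and its levels were already 21.7 ± 6.39 in MLL-AF6 (0.68) and 30.8 ± 3.02 in MLL-AF1p (0.10, not passing) under DMSO. The small Mmp9 rise in MLL-AF6 did not pass without MLL-AF6 DMSO replicate 1 (0.45, limma, Benjamini-Hochberg adjusted p = 0.0913) or MI-2-2 replicate 3 (0.42, adjusted p = 0.105). Stac2 rose by 4.63 in MLL-AF6 and 2.04 in MLL-AF1p and was at 0.05 in MLL-AF9. Osteopontin, Spp1, rose from 13.1 ± 10.7 to 1220 ± 110 in MLL-AF6 (6.75), from 9.84 ± 0.685 to 429 ± 11.7 in MLL-AF1p (5.38) and from 56.7 ± 55.3 to 199 ± 85.2 in MLL-AF9 (2.20). The Spp1 values moved with single DMSO libraries, to 2.98 and 1.5 in MLL-AF9 without its replicate 1 or 2, and to 7.35 in MLL-AF6 without its replicate 1. Oas2 and Rtp4, described with the interferon genes, complete the 6 genes of largest range.

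For the fusion targets, the response of Meis1 was larger in MLL-AF9 than in MLL-AF6 (difference −0.33) and MLL-AF1p (−1.0), and larger in MLL-AF6 than in MLL-AF1p (−0.66; limma, Benjamini-Hochberg adjusted p under 0.05 in all 3). Hoxa9 fell less in MLL-AF9 than in MLL-AF6 (difference 0.98, limma, Benjamini-Hochberg adjusted p = 0.000342), more in MLL-AF6 than in MLL-AF1p (−0.84), and did not differ between MLL-AF9 and MLL-AF1p (0.14, adjusted p = 0.529). Hoxa10 differed by 1.09, 0.73 and −0.36 for the 3 pairs, Myb by −0.36, −1.32 and −0.96, and Id2 by 0.48, 2.63 and 2.15. Under DMSO, Hoxa9 and Hoxa10 were lower in MLL-AF9 than in MLL-AF6 (−1.10 and −0.86), and their treated levels were similar. Their smaller fall in MLL-AF9 is thus not separable from a lower start. Meis1 also started lower in MLL-AF9 (−2.26) but fell more. Mef2c differed by 3.76 between MLL-AF9 and MLL-AF6 and by 3.29 between MLL-AF9 and MLL-AF1p. The response of the 24 MLL fusion targets was higher in MLL-AF9 than in MLL-AF6 as a list, with 12 genes higher and 2 lower (median difference 0.49, camera in limma, Benjamini-Hochberg adjusted p = 0.0104, and 0.537 with an estimated correlation).

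By number, 5937 genes had a response that differed between constructs (F test in limma, Benjamini-Hochberg adjusted p under 0.05), and 915 of them were called in opposite directions in 2 constructs. The pairs gave 3716 genes for MLL-AF9 against MLL-AF6 (2702 higher and 1014 lower), 3939 for MLL-AF9 against MLL-AF1p (2407 and 1532), and 3495 for MLL-AF6 against MLL-AF1p (1308 and 2187). With median centring the MLL-AF9 against MLL-AF6 split became 1302 and 1676 and the MLL-AF9 against MLL-AF1p split 1653 and 2379, so the side of the majority depends on the scaling. The median difference over all genes between MLL-AF9 and MLL-AF6 moved from 0.144 to −0.0191. Of 66 list tests of a differing response, 24 passed with a preset correlation and 0 with an estimated one.

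The last question was how the constructs differ before treatment. Thy1 was 4.33 ± 2.14 in MLL-AF9 DMSO, 1020 ± 298 in MLL-AF6 and 647 ± 22.6 in MLL-AF1p (SD, n = 3). Meis1 was lower in MLL-AF9 than in MLL-AF6 (−2.26) and MLL-AF1p (−1.98), as were Hoxa9 (−1.10 and −1.11) and Hoxa10 (−0.86 and −0.88). Hoxa9 did not differ between MLL-AF6 and MLL-AF1p (−0.00, limma, Benjamini-Hochberg adjusted p = 0.978). Erdr1 was 0.208 ± 0.223, 127 ± 11.2 and 56.5 ± 5.53, and the interferon-inducible gene Pyhin1 was 0.528 ± 0.231, 67.6 ± 9.45 and 31.5 ± 2.19. Xist, the RNA of the inactive X chromosome, was 0.162 ± 0.00841 in MLL-AF9, 20.9 ± 6.51 in MLL-AF6 and 50.1 ± 4.47 in MLL-AF1p, and the Y-linked genes Eif2s3y, Kdm5d and Uty were listed at 0 in every library. Mab21l2 (52.1 ± 5.79, 0.422 ± 0.185 and 0.989 ± 0.0854), the villin-like gene Vill (26.1 ± 3.12, 0.0300 ± 0.0307 and 0.190 ± 0.0278) and the testis proteasome subunit gene Psma8 (21.5 ± 2.61 and 0.0404 ± 0.0188, and listed at 0 in MLL-AF1p) were highest in MLL-AF9.

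Between MLL-AF6 and MLL-AF1p under DMSO, Mpo was lower in MLL-AF6 (0.185 ± 0.193 against 35.4 ± 9.18; SD, n = 3; −5.71), as was the meiotic cohesin gene Stag3 (0.0801 ± 0.0450 against 10 ± 2.28; −4.16). Rps4y2, a ribosomal protein gene with close paralogs, was 5.95 ± 1.19 in MLL-AF1p and listed at 0 in MLL-AF6. The actin-severing gene Scin (8.98 ± 4.62 against 0.160 ± 0.0588; 3.72), the transporter gene Slco4a1 (314 ± 289 against 25.6 ± 7.02; 3.12) and the casein gene Csn2 (324 ± 280 against 28.4 ± 5.26; 2.98) were higher in MLL-AF6. The Csn2 call (limma, Benjamini-Hochberg adjusted p = 0.0185) ended without MLL-AF6 DMSO replicate 1 (adjusted p = 0.0935), replicate 3 (0.0556) or MLL-AF1p DMSO replicate 2 (0.0531). Without MLL-AF6 DMSO replicate 1 or 2 the difference was 2.26 or 3.89 for Csn2 and 2.35 or 3.94 for Slco4a1. Of the partner genes, Mllt3 was 2.30 ± 0.211 in MLL-AF9, 0.739 ± 0.155 in MLL-AF6 and 1.48 ± 0.102 in MLL-AF1p, Mllt4 was 0.621 ± 0.120, 3.81 ± 0.119 and 3.50 ± 0.439, and Eps15 was 11.2 ± 2.00, 12.8 ± 0.727 and 16.4 ± 0.927.

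Under DMSO, 6021 genes differed between MLL-AF9 and MLL-AF6 (2752 higher and 3269 lower in MLL-AF9), 7318 between MLL-AF9 and MLL-AF1p (3213 and 4105), and 5900 between MLL-AF6 and MLL-AF1p (2665 and 3235; limma, Benjamini-Hochberg adjusted p under 0.05). With median centring the first 2 splits turned to 3326 and 2662, and 3807 and 3431, so the side of the majority depends on the scaling. At 2-fold or more the counts were 522 and 527, 580 and 851, and 216 and 377. The MLL fusion target list was lower in MLL-AF9 than in MLL-AF6, with 4 genes higher and 11 lower (camera in limma, Benjamini-Hochberg adjusted p = 0.0251, and 0.977 with an estimated correlation). The cell cycle list was lower in MLL-AF6 than in MLL-AF1p, with 0 genes higher and 29 lower (camera in limma, Benjamini-Hochberg adjusted p = 1.47e-07, and 0.725 with an estimated correlation). Since no cell sources of one construct were compared, a difference between constructs is not separable from a difference between the cultures.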

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

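The tests on the interferon genes, on the gene properties of the axis within groups and on the cell cycle genes were chosen only after the result was seen, and the other tests of this part were written before.

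Interferon response genes rose in MLL-AF9 and not in MLL-AF6 cells, with a mean difference of log2 fold changes of 2.15 over 24 genes. One library might have made the difference, but leaving out each of the 18 in turn gave at least 1.99, the lowest without MLL-AF9 MI-2-2 replicate 1. Scaling gave 1.99 with median centring and 2.01 with quantile normalization, so neither accounts for it. Different starting levels brought to one level by MI-2-2 are not what was measured, since the list differed by −0.619 between MLL-AF9 and MLL-AF6 under DMSO (lower in MLL-AF9) and by 1.54 under MI-2-2 (higher). What else may set the constructs apart, such as the state of the cultures, was not tested.

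Libraries of one group differed along one axis that held 49.5% of the variance within groups, and replicate 1 lay above replicate 2 in 6 of 6 groups. Slc6a12, Csn2, Hdc, Slco4a1 and Fam167b were higher in replicate 1 in 6 of 6 groups, and Trib3, Mt2 and P2rx3 in replicate 2. S100a4 was higher in replicate 1 in 5 of 6 groups, and Bzrap1, Stc2 and Chac1 in 1 of 6. All these genes were taken for their large weight on the axis, so their order by number is in part built in. GC content, length and level of the genes accounted for 5.48% of the axis, which leaves little to these properties. Depth is unlikely too, since after thinning to the smallest library the axis still held 45.2%. No biological explanation was tested, and day or handling may lie behind it.

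Of 78 ribosomal protein genes, 76, 73 and 71 fell in MLL-AF9, MLL-AF6 and MLL-AF1p, with medians of −0.991, −0.483 and −0.492. Scaling between libraries might lower them, but against level-matched genes the medians were −1.01, −0.489 and −0.565, which no factor per library can move. After trends on length, GC content and level were removed they were −1.22, −0.718 and −0.725. Fewer dividing cells would be expected to lower cell cycle genes too, but among 34 such genes 24, 11 and 8 were called higher and 0, 1 and 2 lower in MLL-AF9, MLL-AF6 and MLL-AF1p. The cause of the fall was not tested further, and shares of RPKM do not give amounts per cell.

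Several named genes were called in opposite directions in 2 constructs with a difference that passed. Between MLL-AF9 and MLL-AF6 the effect of MI-2-2 differed by 4.52 for Oas2. For Rtp4 this difference was 4.46. For Pyhin1 it was 4.01, with DMSO levels far lower in MLL-AF9. Mef2c differed by 3.76 between the same constructs. Cdkn1c differed by −3.46. Pf4 differed by −2.66. Mll1 differed by 0.69. Between MLL-AF9 and MLL-AF1p, Mllt4 differed by 1.77 and Vill by −0.94. Between MLL-AF6 and MLL-AF1p, Bop1 differed by −1.34 and Hcfc1 by −0.69. Of the 131 named genes, 109 had a response that differed between constructs by the F test in limma (Benjamini-Hochberg adjusted p under 0.05). Over all 11238 genes tested the count was 5937 (52.8%). A higher share among named genes is expected, because the rule picks genes by size of change and by range of response in these same data. With 3 libraries per group no library was tested as an outlier.

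Other ways of splitting the libraries were run for the counts named here, and not for opposite calls or 2-fold counts. For MI-2-2 against DMSO in each construct there are 10 splits of 6 libraries, too few for a share under 0.05: fitted alone, the real split called 4875, 5838 and 6852 genes and the highest other 0 in MLL-AF9, MLL-AF6 and MLL-AF1p, so the real split was the 1 of 10 that reached its count. The same holds for the DMSO comparisons, with 3691, 5881 and 5289 genes against 0. For genes changed the same way in all 3 constructs, the real grouping gave 2247 genes and the others 0 at most (1 of 100 as high, the real one). This ties the count to the treatment labels of these libraries. It tests neither the sharing between constructs nor chance between cultures, since mixing treated and control libraries in some construct lowers the count by itself. For differing responses fewer than 5 of 100 splits reached the real count, but these splits mix libraries of constructs that differ under DMSO, which are not exchangeable, so this is not taken to exclude chance. The values were 5937 against 4097 by the F test (1 of 100 as high), 2672 against 1882 for MLL-AF9 and MLL-AF6 (1), 3880 against 4369 for MLL-AF9 and MLL-AF1p (2), and 4190 against 7607 for MLL-AF6 and MLL-AF1p (2), and the higher counts of single splits point to structure among the samples. For the number of gene lists called, chance cannot be excluded, with 26 against 27 and 5 of 100 at least as high. This test cannot decide the question, because 3 treated libraries never split evenly over groups of 3. Every other grouping thus keeps part of the treatment difference, and camera compares the genes of a list with the other genes. The median of the other groupings was 22 list tests, so with the preset correlation most groupings called nearly as many. With an estimated correlation the real grouping called 6 lists and the highest other 0.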

How the results depend on the processing

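The tests with voom, thinned reads and libraries numbered 1 or 2 left out were chosen only after the result was seen, and the other alternatives were planned. Of the named-gene tests of MI-2-2 or under DMSO and the MI-2-2 list tests that passed, none turned direction under the alternatives run for it, while named differences of response and other list tests were not run under them, and the majority of rises or falls over all genes turned in several comparisons with median centring. The planned count test on counts was not run in that form, because the values are RPKM, and voom on recovered reads stands in its place. With 1 library left out at a time, rises and falls were 2879–3399 and 2736–3238 in MLL-AF9, 1774–2180 and 3710–4697 in MLL-AF6, 1726–2396 and 2379–3355 in MLL-AF1p, and 870–1040 and 1078–1432 in all 3. Differing responses were 5069–6784 by the F test, 3056–4609 (MLL-AF9 against MLL-AF6), 3144–4407 (MLL-AF9 against MLL-AF1p) and 2784–4224 (MLL-AF6 against MLL-AF1p), DMSO differences 5306–6519, 6717–7490 and 4948–6514, and lists 25–29. The 3495 differing responses between MLL-AF6 and MLL-AF1p fell to 2230 without libraries numbered 1. The 26 lists called became 6 with an estimated correlation and 49 with fry, so most list calls depend on the assumed correlation. The erythroid and megakaryocyte call in MLL-AF6 (adjusted p = 0.0428 by camera in limma) was lost without MLL-AF9 DMSO replicate 2 (0.0556), MLL-AF6 DMSO replicate 1 (0.0531) or MLL-AF1p DMSO replicate 2 (0.0555), with 0.119 the highest of the alternatives at a preset correlation. Opposite calls in MLL-AF9 and MLL-AF6 were 641 without MLL-AF9 DMSO replicate 1, those in MLL-AF6 and MLL-AF1p 249 without MLL-AF1p MI-2-2 replicate 1, and the 3 pairs gave 269, 246 and 235 without libraries numbered 1. Of 345 named-gene results called, 17 lost the call without some 1 library, among them Kit in MLL-AF9 and Cd14 in MLL-AF9 and MLL-AF1p. Depth limits low genes most, since 1 read weighs more in the MLL-AF9 and MLL-AF6 libraries.

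Replicate numbers are shared by groups without a statement of pairing. After group means were removed, 11 of 18 libraries correlated best with their own number, each among 3 libraries of the other treatment (5 of 9 pairs over 0.1, r from 0.00079 to 0.557 across genes, which are not independent replicates). Libraries numbered 2 matched each other best in all 3 constructs (r = 0.46, 0.557 and 0.21 in MLL-AF9, MLL-AF6 and MLL-AF1p). Those numbered 3 barely correlated (r = 0.0139, 0.00079 and 0.0261). Some libraries of one number thus share part of their spread, which the main fit does not model. With a block for the number, rises and falls were 3479 and 3438 in MLL-AF9, 2250 and 4816 in MLL-AF6, 2446 and 3488 in MLL-AF1p, and 1107 and 1546 in all 3. Differing responses were 6986 by the F test and 4500, 4831 and 4292 by pair, DMSO differences were 6712, 7800 and 6525, and 25 lists passed. With the block, Trib3 passed in MLL-AF9 and MLL-AF1p (limma, adjusted p = 0.0186 and 0.0444), Cd14 in MLL-AF6 (0.00261) and Myc in MLL-AF1p (0.0025). Over all 432 tests of named genes, 16 gained a call and 1 lost it. The erythroid and megakaryocyte list lost its call in MLL-AF6 (camera in limma, adjusted p = 0.0677). The cause of the gain with the block was not tested.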

Other observations

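The tests of the immediate early and lysosomal lists were chosen only after the result was seen.

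Immediate early genes, which cells switch on within minutes of a signal, were higher after 6 days with MI-2-2. Fos rose from 0.592 ± 0.101 to 88.7 ± 2.77 RPKM in MLL-AF9 (6.36), from 0.558 ± 0.205 to 51.6 ± 4.39 in MLL-AF6 (5.64) and from 0.373 ± 0.0418 to 11.9 ± 0.575 in MLL-AF1p (3.83; SD, n = 3). Egr1 rose by 6.10, 5.43 and 4.26, Jun by 3.73, 2.85 and 2.67, and Zfp36, which destabilizes cytokine messages, by 2.96, 1.32 and 1.32. Of 17 further immediate early genes, without Fos and Egr1, 16 rose in MLL-AF9, 15 in MLL-AF6 and 14 in MLL-AF1p, and 0 fell. Those not passing were Maff in MLL-AF9, Fosl2 and Jund in MLL-AF6, and Fosl2, Klf2 and Maff in MLL-AF1p. The list of 17 was called higher in each construct by camera in limma with a preset correlation (Benjamini-Hochberg adjusted p = 6.42e-11, 2.16e-10 and 1.56e-06) and with an estimated one (adjusted p = 0.0045, 0.0045 and 0.0196), with medians of 1.99, 1.18 and 0.698.

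Lysosomal genes rose with the macrophage markers in single genes. Psap, a precursor of lipid-degrading cofactors, rose from 37.5 ± 3.44 to 309 ± 20.2 in MLL-AF9 (3.03), and by 3.33 in MLL-AF6 and 2.27 in MLL-AF1p (SD, n = 3). The protease genes Ctsb (2.1, 2.6 and 1.5), Ctsd (1.05, 1.8 and 1.19) and Lgmn (3.82, 6.46 and 4.82) rose in all 3 constructs, and Gaa fell (−0.30, −0.45 and −0.54). Of 30 lysosomal genes, 26, 27 and 15 rose and 1, 1 and 3 fell. As a list they were called higher with a preset correlation (camera in limma, Benjamini-Hochberg adjusted p = 1.7e-09, 9.48e-14 and 1.75e-05) and not with an estimated one (adjusted p = 0.128, 0.0726 and 0.243), so whether lysosomal genes rise as a set stays open.

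As a hypothesis, not tested here, the rise of immediate early genes (camera in limma, adjusted p of at most 0.0196) may reflect a steady state of the changed cells or handling shortly before lysis, which a time course would separate. These values come from polyA RNA of whole cultures, in which a change of cell types and a change within cells look alike.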
